A study of Mus musculus with 17 samples.

How the data were processed

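RNA-seq was analysed in 12 mouse libraries: 4 of YAP-M tumours, 3 of YAP-M-dIDR, 3 of SVZ and 2 of NSC-YAP. The series has 17 samples, and its 5 ChIP-seq and CUT&RUN samples, which measure where proteins bind to DNA, were not analysed here. Per the labels' protocols, RNA was extracted with TRIzol and an RNeasy kit, and libraries were made from total RNA with an Illumina TruSeq RNA kit. Groups and replicate numbers were taken from the sample titles.

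The deposited tables hold whole-number counts per gene, 1 library each, with no normalization, and every library had its own total. Per the submitters' processing notes, reads were aligned with TopHat2 and the build was mm10. The versions, the counting program, its use of strand and of reads that map to several places, and the annotation release are not given in the sources used here. Reads of paralogs, overlapping genes and antisense partners may therefore be split or shared between genes. Each table lists 53090 genes by Ensembl identifier with chromosome, start, end, strand and symbol, and these coordinates are the ones printed. A symbol stood on several lines for 453 entries, which were summed to give 52850 symbols. Such entries held 1.29% of the counts in the median library, and 540 entries lay outside the named chromosomes. The files use older symbols for Ccn1 (Cyr61), Ccn2 (Ctgf) and Dnai1 (Dnaic1).

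Counts were turned into CPM values with library sizes scaled by the TMM factors of edgeR, which ranged from 0.826 to 1.13. Total counts per library, from 20784130 to 25463303, set the precision. A level that gives 3 counts in a library corresponds to 0.11 to 0.147 CPM. Where a group had no count, a fold change was bounded from below with a floor of 3 counts over that group. With 1 to 3 counts the ratio was given with an exact 95% interval from counting error. Intervals and floors cover counting error only, since reads amplified by PCR are not independent molecules.

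Genes with at least 1 CPM in at least 2 libraries were tested, which left 18329 genes. The test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on the summed counts, with 1 coefficient for each of the 4 groups and all 12 libraries in 1 fit. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called with an adjusted p under 0.05 and a log2 fold change of at least 1 in size. Values after ± are standard errors of the log2 fold change where SE is named or a fold change precedes them, and standard deviations over libraries for levels. The 5 comparisons were YAP-M tumour against SVZ, YAP-M-dIDR and NSC-YAP, and YAP-M-dIDR against NSC-YAP and SVZ.

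The comparisons, 22 gene lists with 322 different genes (304 tested), the tests, the alternatives and the rule for named genes were fixed before the data were examined. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the 22 lists of a comparison, and again with the correlation estimated from the data. The number of called members was also counted with p-values adjusted over the list alone. Named genes were the 8 largest rises and 8 largest falls in each comparison of the YAP-M tumours and the 4 and 4 largest in the other comparisons, among called genes whose groups did not overlap, with a mean of at least 5 CPM in the higher group and a symbol that is neither predicted nor unnamed. Up to 4 members of each list with the smallest adjusted p, and Yap1, Mamld1, Ccn1, Ccn2 and Ankrd1 in every comparison, were named as well. Some genes that this rule names are not reported here. Genes outside this rule, in the other observations, were chosen after their values were seen.

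Yap1 was compared by exact 2-sided permutation tests of log2(CPM + 1). Correlations between libraries and principal components used log2(CPM + 1) of the tested genes. No replicate pair agreed within sampling noise, with a chi-square per gene of 4.17 (the NSC-YAP pair) to 84.2, so each library was entered as 1 sample. Separate preparations of 1 sample can also exceed sampling noise, so this does not show that the samples were separate. The design fixed in advance foresaw limma for normalized values and edgeR for counts; the tables held counts, so edgeR was used. The alternatives were no filter, a minimum of 5 CPM (14554 genes), median-ratio scaling, quantile normalization with limma, no abundance trend in the dispersion, the replicate number as a block, the entry with the highest mean for each symbol, the compared groups alone, the adjusted p alone, DESeq2 1.42.0 and leaving out each library in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

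The tests were tried on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. For YAP-M tumour against SVZ (17814 genes) 32 and 89 of them were recovered, against YAP-M-dIDR (17955 genes) 39 and 91, and against NSC-YAP (17843 genes) 31 and 84. For YAP-M-dIDR against NSC-YAP (17905 genes) 25 and 83 were recovered, and against SVZ (17790 genes) 36 and 88. Between 3 and 8 unchanged genes were called in each, and none of the 22 lists. The simulated genes were drawn independently of each other. The absence of list calls therefore does not show how the list test behaves where members move together.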

Results

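Gene expression was measured by RNA-seq in 12 mouse libraries from a study of YAP fusion proteins in supratentorial ependymoma, a tumour of the forebrain. YAP, the product of Yap1, is a transcriptional coactivator that is restrained by the Hippo kinase pathway and binds DNA through TEAD transcription factors. The YAP-M tumour group held 4 libraries of brain tumours that followed in utero electroporation, the delivery of plasmid DNA into the embryonic brain, with a construct named YAP-M. The YAP-M-dIDR group held 3 libraries made with a construct named YAP-MΔIDR, and the SVZ group held 3 libraries of wild-type samples. The NSC-YAP group held 2 libraries of neural progenitor cells derived from embryonic stem (ES) cells that overexpressed YAP. The labels of the YAP-M-dIDR libraries name both brain tumour tissue and ES-derived neural progenitor cells, and those of the SVZ libraries name both wild-type treatment and brain tumour, so the material of these groups was not settled from the labels. Nothing in the labels says that replicates came from separate animals or cultures. p-values measure the spread between these samples, part of which may be technical. For edgeR and camera this spread was estimated over all 4 groups, so comparisons of more variable groups can get p-values that are too small.

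Total counts per library ranged from 20784130 in YAP-M tumour replicate 3 to 25463303 in NSC-YAP replicate 1. Mitochondrially encoded genes took 4.91% to 6.50% of the counts in the YAP-M tumour libraries, 5.55% to 6.03% in YAP-M-dIDR, 6.97% to 7.05% in NSC-YAP and 12.7% to 16.98% in SVZ. Transcripts tied to sex differed within 3 of the groups, so their libraries were not all repeats of 1 sample. Xist, the X-inactivation RNA, stood at 1.02 CPM in YAP-M tumour replicate 3 and at 354 to 360 CPM in the other YAP-M tumours, and the Y-linked gene Ddx3y at 81.7 CPM against 0.0368 to 0.111 CPM. In YAP-M-dIDR replicate 3 Xist stood at 22.7 CPM and Ddx3y at 69.9 CPM, against 288 and 396 CPM of Xist and 0 and 0.135 CPM of Ddx3y in the others. SVZ replicate 2 had 415 CPM of Xist and 4.54 CPM of Ddx3y, against 0.460 and 27.3 CPM of Xist and 63.3 and 72.1 CPM of Ddx3y in the others. Both NSC-YAP libraries had Ddx3y, at 47.99 and 50.4 CPM. No term for sex was fitted.

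The first principal component of log2 CPM, the count relative to the scaled library size, held 59.7% of the variance and the second 27.9%. Across genes, which are not independent replicates, the median Spearman correlation was 0.979 between YAP-M tumour libraries, 0.964 between YAP-M-dIDR libraries and 0.940 between these groups. It was 0.739 between YAP-M tumour and SVZ, 0.754 between YAP-M tumour and NSC-YAP, and 0.755 between YAP-M-dIDR and NSC-YAP.

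**Figure D1:**
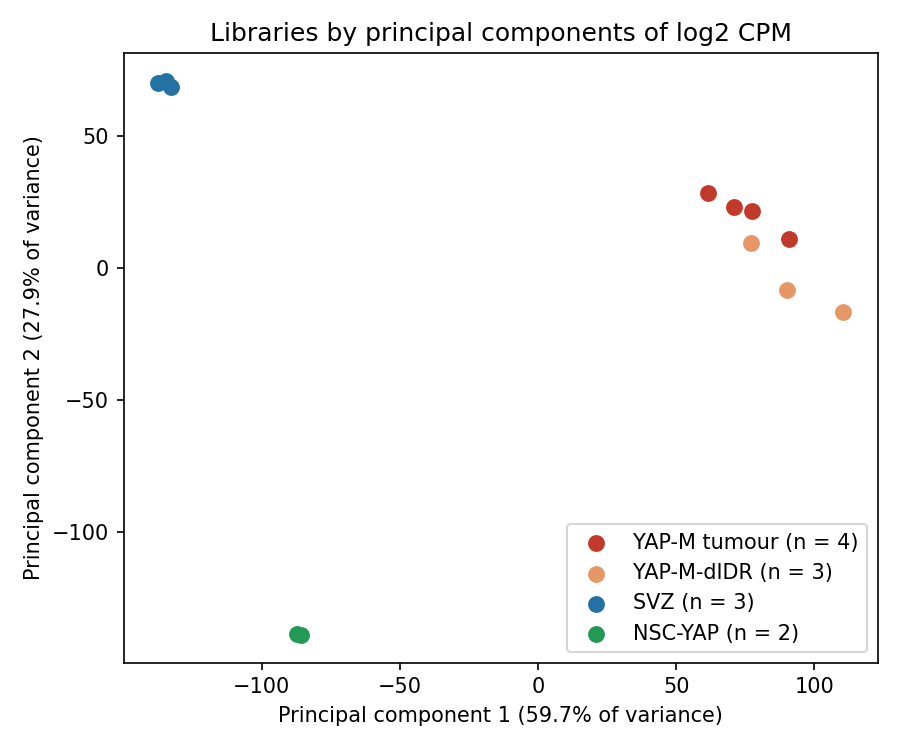
Each point is 1 of the 12 libraries, placed by its first (59.7% of variance) and second (27.9% of variance) principal component of log2 CPM, coloured by group. The YAP-M tumour and YAP-M-dIDR libraries lie on 1 side of the first component and the SVZ and NSC-YAP libraries on the other.

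Yap1 (ENSMUSG00000053110, mm10 chromosome 9, 7931999 to 8004596, minus strand) was measured first, because the constructs carry YAP sequence. Its level was 24.9 ± 3.19 CPM (SD, n = 3) in SVZ, 97.2 ± 5.77 CPM (SD, n = 4) in YAP-M tumours, 240 ± 2.13 CPM (SD, n = 2) in NSC-YAP and 765 ± 549 CPM (SD, n = 3) in YAP-M-dIDR. The YAP-M-dIDR libraries spread widely, with 184 CPM in replicate 1, 838 CPM in replicate 2 and 1274 CPM in replicate 3. YAP-M tumours exceeded SVZ, and YAP-M-dIDR exceeded YAP-M tumours, each with an exact 2-sided permutation p = 0.0286, the smallest that 35 splits allow. The exact permutation p was 0.0667 for YAP-M tumour against NSC-YAP and 0.1 for YAP-M-dIDR against SVZ, each the smallest its design allows. For YAP-M-dIDR against NSC-YAP it was 0.4, because replicate 1 lay below both NSC-YAP libraries. The species of the construct is not given in the labels, so construct reads may have been counted on Yap1 only in part.

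The comparison of YAP-M tumour with SVZ asked how the tumours differ from the wild-type samples. Called higher in the tumours were 18 of 22 YAP/TEAD target genes, all 18 cell cycle genes, 20 of 22 extracellular matrix genes, 14 of 16 macrophage genes and 18 of 19 interferon response genes. Called lower were 16 of 17 neuronal, 11 of 12 oligodendrocyte and 14 of 19 multiciliated cell genes, and each of these list calls was lost with an estimated correlation (adjusted p = 0.122 to 0.595). Ankrd1 (ENSMUSG00000024803, mm10 chromosome 19, 36111965 to 36119844), a muscle ankyrin repeat protein and classical YAP target, stood at 1144 ± 145 CPM (SD, n = 4) in the tumours and 0.530 ± 0.645 CPM (SD, n = 3) in SVZ, or 0.160 CPM without SVZ replicate 3. Ctgf (Ccn2, ENSMUSG00000019997, mm10 chromosome 10, 24595442 to 24598683), a secreted matricellular protein, stood at 895 ± 79.6 CPM (SD, n = 4) against 10.7 ± 0.703 CPM (SD, n = 3), and its relative Cyr61 (Ccn1, ENSMUSG00000028195, mm10 chromosome 3, 145646976 to 145649981) at 961 ± 106 CPM (SD, n = 4) against 9.16 ± 1.55 CPM (SD, n = 3). Of 18329 genes tested with edgeR, 4722 were called higher and 5296 lower in the tumours.

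Of 22 YAP/TEAD target genes, 18 rose, 2 fell and 2 were not called (median log2 fold change 2.92, camera adjusted p = 4.22e-07, adjusted p = 0.122 with an estimated correlation). Ankrd1 rose by 11.10 ± 0.64 (log2, SE), Cyr61 by 6.71 ± 0.17 and Ctgf by 6.39 ± 0.27. Amotl2, which encodes an angiomotin family scaffold that binds YAP, rose by 5.02 ± 0.15, and the Hippo kinase gene Lats2 by 3.23 ± 0.12. Of 18 Hippo pathway components, 13 rose and 5 were not called (median 1.95, camera adjusted p = 4.42e-06, adjusted p = 0.297 with an estimated correlation). Those that rose included the transcription factor gene Tead1 (4.01 ± 0.20) and the scaffold gene Amot (4.20 ± 0.24). Yap1 itself rose by 1.97 ± 0.47 (edgeR adjusted p = 0.00247). Mamld1 (ENSMUSG00000059401, mm10 chromosome X, 71050256 to 71156056), which encodes a mastermind-like domain protein, was not called, with a log2 fold change of 0.64 ± 0.15. If the constructs hold Mamld1 sequence, its reads may have been counted here in full, in part or not at all. The Mamld1 values of every comparison carry this limit.

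**Figure D2:**
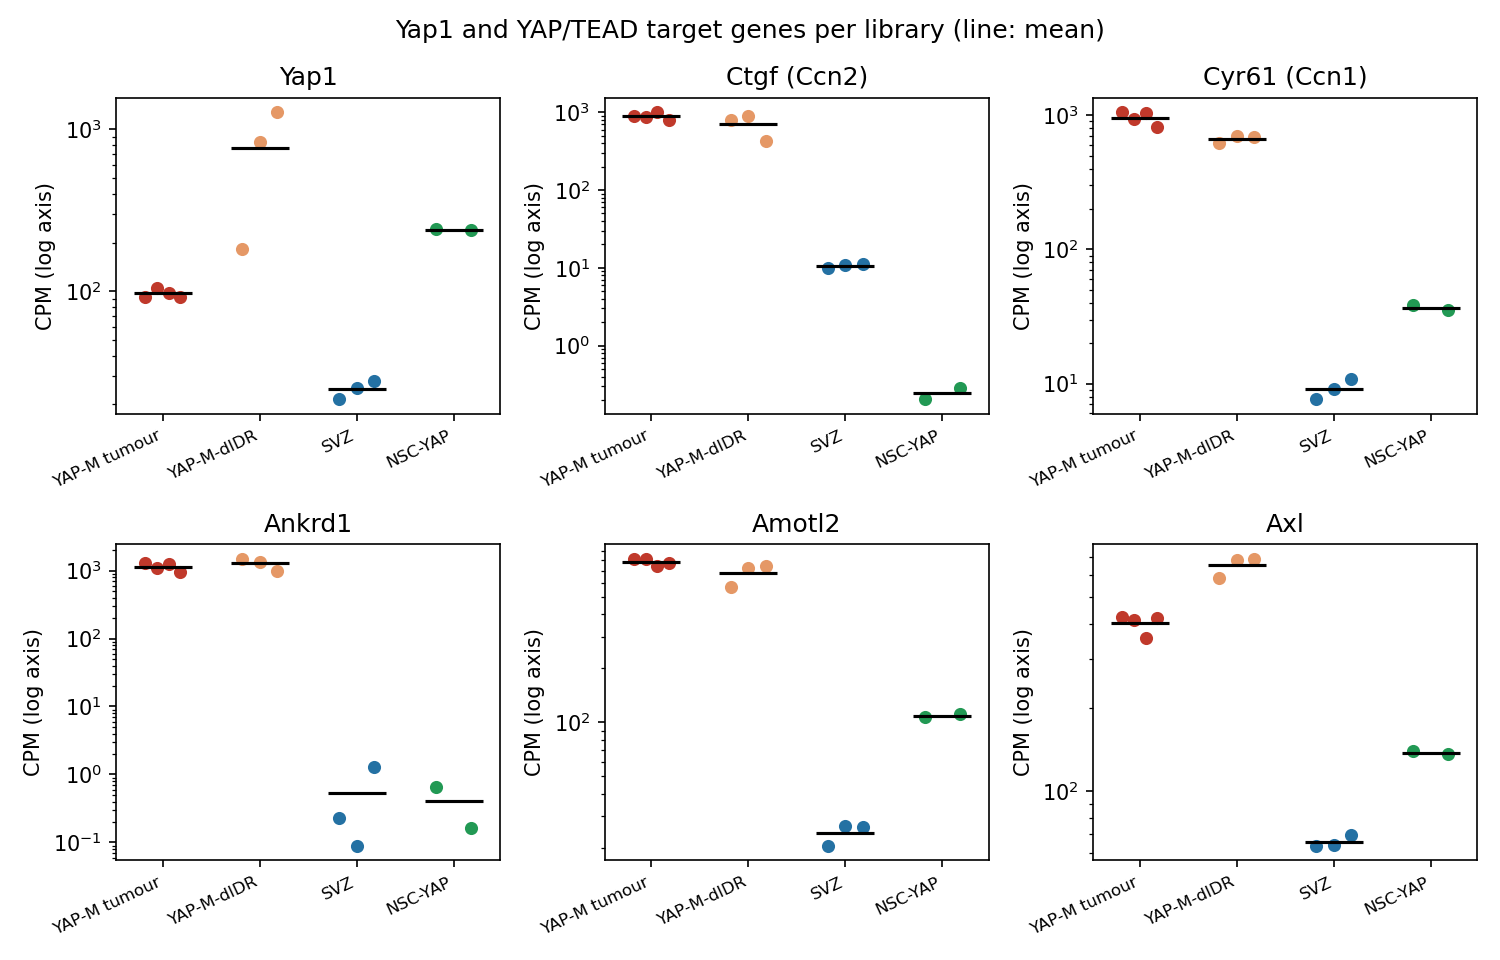
Each point is 1 library and each line a group mean, in CPM on a log axis, for Yap1 and 5 YAP/TEAD target genes in the 4 groups. Ankrd1 averages 1144 CPM in the YAP-M tumours and 1282 CPM in YAP-M-dIDR, and 0.530 CPM in SVZ and 0.407 CPM in NSC-YAP.

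All 18 cell cycle genes rose (median 3.48, camera adjusted p = 1.21e-07, adjusted p = 0.32 with an estimated correlation), among them the replication helicase gene Mcm6 by 2.72 ± 0.12 and the ribonucleotide reductase gene Rrm2 by 4.59 ± 0.29. Of 22 extracellular matrix and mesenchymal genes, 20 rose (median 3.70, camera adjusted p = 4.22e-07, adjusted p = 0.205 with an estimated correlation). Thbs1, which encodes thrombospondin, rose by 8.18 ± 0.32 to 1275 ± 274 CPM (SD, n = 4), and Fn1, which encodes fibronectin, by 5.29 ± 0.22. Of 17 growth factor receptor and growth control genes, 11 rose and 2 fell (median 1.35, camera adjusted p = 0.00464, adjusted p = 0.152 with an estimated correlation). The ephrin receptor gene Epha2 rose by 5.67 ± 0.19, the transcription factor gene Myc by 4.32 ± 0.15 and the hepatocyte growth factor receptor gene Met by 5.43 ± 0.26. Of 12 immediate early and stress genes, 7 rose and 1 fell (median 1.96, camera adjusted p = 0.00838, adjusted p = 0.32 with an estimated correlation). Of 11 p53 target genes 7 rose (median 1.28, camera adjusted p = 0.0044, adjusted p = 0.586 with an estimated correlation). Glycolysis and hypoxia genes moved both ways, 6 higher and 2 lower of 15 (camera adjusted p = 0.107), with the hexokinase gene Hk2 up by 3.88 ± 0.13 and Hk1 at -1.13 ± 0.07, a call lost with no filter on low counts (-0.99). Of 14 transcription coactivator and condensate-associated genes, only Maml1 was called (1.34 ± 0.16; camera adjusted p = 0.962).

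Genes of other cell types moved with these groups. Of 16 microglia and macrophage genes, 14 rose (median 2.83, camera adjusted p = 2.3e-05, adjusted p = 0.32 with an estimated correlation), including the lysozyme gene Lyz2, at 837 ± 221 CPM (SD, n = 4) against 5.94 ± 2.19 CPM (SD, n = 3). Of 19 interferon response and antigen presentation genes, 18 rose (median 3.28, camera adjusted p = 5.15e-06, adjusted p = 0.32 with an estimated correlation), with the class I antigen gene H2-D1 up by 4.08 ± 0.21. Of 17 neuronal genes, 16 fell (median -3.75, camera adjusted p = 6.79e-05, adjusted p = 0.297 with an estimated correlation), among them the microtubule protein genes Map2 (-3.12 ± 0.31) and Dcx (-2.81 ± 0.15). Of 12 oligodendrocyte lineage genes, 11 fell (median -3.76, camera adjusted p = 0.00173, adjusted p = 0.563 with an estimated correlation), and Mbp, the gene of myelin basic protein, stood at 725 ± 517 CPM (SD, n = 4) against 14150 ± 1676 CPM (SD, n = 3). Of 19 multiciliated ependymal cell genes measured, 14 fell and none rose (median -2.32, camera adjusted p = 0.00337, adjusted p = 0.595 with an estimated correlation), including the transcription factor gene Rfx3 (-3.06 ± 0.16) and the axonemal dynein gene Dnaic1 (Dnai1, -4.28 ± 0.47).

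The other lists did not pass the camera test. Radial glia and neural stem cell genes split into 4 higher and 7 lower of 14 (camera adjusted p = 0.962): Vim, an intermediate filament gene, rose by 5.26 ± 0.17, Egfr by 3.60 ± 0.19 and Nes, the nestin gene, by 2.47 ± 0.20, while Ptprz1 was lower at -1.90 ± 0.13. Notch pathway genes had 2 higher and 7 lower of 13 (camera adjusted p = 0.189), astrocyte genes 1 and 6 of 10 (0.0959), blood cell genes 2 and 7 of 9 (0.0959) and choroid plexus genes 0 and 5 of 9 (0.146). Endothelial and pericyte genes had 4 and 1 of 12 (camera adjusted p = 0.151), lymphocyte genes 1 and 1 of 3 measured (0.873) and pluripotency genes 2 and 1 of 3 measured (0.962). The hemoglobin paralogs among the blood cell genes may share reads, so their single values are uncertain.

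The largest rises outside these lists, ordered by fitted fold change, were at genes with almost no counts in SVZ, where the order and the fold rest on counts near 0. Nkx2-6, a homeobox gene, was at least 643-fold higher, Tnfsf4 at least 363-fold and the homeobox gene Evx2 at least 256-fold, against a floor of 3 counts over the SVZ group. Hoxd13 (ENSMUSG00000001819, mm10 chromosome 2, 74668310 to 74671599), a homeobox gene of posterior body structures, was 4280 times higher (95% counting interval 768 to 169100), the platelet chemokine gene Ppbp 8110 times (1455 to 320400) and Krtap1-5 2801 times (775 to 23130). The channel gene Panx3 rose by 11.20 ± 0.44. Among the largest falls were Dlx6os1 (-6.00 ± 0.41), the dopamine receptor gene Drd2 (-5.99 ± 0.45) and Syndig1l (-5.95 ± 0.51), followed by Ido1 (-5.92 ± 0.61), the activity-regulated gene Arc (-5.82 ± 0.44), Gpr6 (-5.78 ± 0.45) and Ankrd63 (-5.74 ± 0.46). Adjusted over the list alone, the counts of higher and lower members equalled those over all genes in each of the 22 lists. No call of any list in any of the 5 comparisons held with an estimated correlation. The mitochondrial share of counts was 12.7% to 16.98% in SVZ against 4.91% to 6.50% in the tumours.

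The comparison of YAP-M tumour with YAP-M-dIDR asked what differs between the full construct and the ΔIDR construct. Of the 22 YAP/TEAD targets, 19 were not called between these groups, while Yap1 itself was higher in YAP-M-dIDR. Targets not called were not all equal, since a call needs a log2 fold change of at least 1 in size. Cyr61 stood at 819 to 1050 CPM in YAP-M tumours against 619.9 to 695.4 CPM in YAP-M-dIDR. Axl differed the other way, at 357.4 to 423 against 585.3 to 689.3 CPM. Called higher in YAP-M tumours were 7 of 9 blood cell genes, 4 of 10 astrocyte genes, 5 of 12 endothelial and pericyte genes and 6 of 14 radial glia genes, with 1 radial glia gene, Nes, lower. Called higher in YAP-M-dIDR were 3 of 19 interferon response genes and the glycolytic genes Eno1 and Gapdh. Each of these list calls was lost with an estimated correlation (adjusted p = 0.62 to 0.752), and those of the radial glia and interferon lists were also lost without single libraries. With edgeR, 1761 genes were called higher and 1242 lower in YAP-M tumours. Quantile normalization called 1035 higher, a minimum CPM of 5 called 819 lower, and the adjusted p alone called 3768 higher and 4199 lower. The fit on the compared groups alone called 1242 higher and 1043 lower. Without YAP-M-dIDR replicate 1 the counts were 2566 higher and 1227 lower.

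Ankrd1 stood at 1144 ± 145 CPM (SD, n = 4) in YAP-M tumours and 1282 ± 261 CPM (SD, n = 3) in YAP-M-dIDR, a log2 fold change of -0.16 ± 0.37 (SE), and its sign turned to 0.16 under quantile normalization. Ctgf differed by 0.34 ± 0.21 and Cyr61 by 0.53 ± 0.12, and neither was called. Of the 22 YAP/TEAD targets, 2 rose, 1 fell and 19 were not called (median 0.36, camera adjusted p = 0.0332, adjusted p = 0.62 with an estimated correlation, and 0.0944 without YAP-M-dIDR replicate 3). Nt5e, which encodes a surface nucleotidase, rose by 2.11 ± 0.18, and Igfbp3, which encodes a growth factor binding protein, by 1.07 ± 0.17, a call lost without YAP-M-dIDR replicate 2 (0.99). Among the 18 Hippo pathway components only Yap1 (-2.98 ± 0.45) and the transcription factor gene Tead2 (-1.69 ± 0.22) were called, both lower (camera adjusted p = 0.529). No transcription coactivator and condensate-associated gene was called, of 14 (camera adjusted p = 0.181), although 8 of them had an edgeR adjusted p under the threshold with a log2 fold change smaller than 1. Mamld1 had a log2 fold change of -0.53 ± 0.15.

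Blood cell genes were higher in YAP-M tumours at 7 of 9 members (median 1.97, camera adjusted p = 0.00759, adjusted p = 0.62 with an estimated correlation), with the heme synthesis gene Alas2 up by 3.66 ± 0.39. Of 10 astrocyte genes, 4 rose, or 5 when adjusted over the list alone (median 1.26, camera adjusted p = 0.00664, adjusted p = 0.748 with an estimated correlation), including Aldh1l1 (1.75 ± 0.23) and the water channel gene Aqp4 (1.27 ± 0.30). Of 12 endothelial and pericyte genes, 5 rose (median 0.75, camera adjusted p = 0.0109, adjusted p = 0.62 with an estimated correlation), including the endothelial adhesion gene Pecam1 (1.11 ± 0.18). Radial glia and neural stem cell genes had 6 higher and 1 lower of 14 (median 0.69, camera adjusted p = 0.037, adjusted p = 0.62 with an estimated correlation): Prom1 rose by 2.31 ± 0.24 and Ptprz1 by 1.14 ± 0.13, while Nes was lower at -1.84 ± 0.18. This call was lost without YAP-M tumour replicate 2 (adjusted p = 0.0605), YAP-M tumour replicate 4 (0.0692) or YAP-M-dIDR replicate 3 (0.0717), and under median-ratio scaling (0.0509). Of 12 oligodendrocyte lineage genes, 1 rose, the growth factor receptor gene Pdgfra by 2.33 ± 0.28 (list median 1.11, camera adjusted p = 0.0468, adjusted p = 0.752 with an estimated correlation). That list call was lost without YAP-M tumour replicate 3 (adjusted p = 0.102) or 4 (0.108, median 0.66) or YAP-M-dIDR replicate 2 (0.234) or 3 (0.0839), and the median was 1.76 without YAP-M-dIDR replicate 1. It was also lost at a minimum CPM of 5 (adjusted p = 0.0542), under median-ratio scaling (0.0559) and with the compared groups alone (0.0508). With the replicate number as a block, the oligodendrocyte and the radial glia list calls were both lost.

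Interferon response and antigen presentation genes were lower in YAP-M tumours at 3 of 19 members (median -0.74, camera adjusted p = 0.0332, adjusted p = 0.752 with an estimated correlation). The call was lost without YAP-M tumour replicate 3 (adjusted p = 0.0755) or YAP-M-dIDR replicate 2 (0.14) or 3 (0.0839). Glycolysis and hypoxia genes had 3 lower of 15 (camera adjusted p = 0.0553, 0.0196 without YAP-M tumour replicate 2 and 0.0112 without YAP-M-dIDR replicate 1), with the enolase gene Eno1 at -1.36 ± 0.11 and Gapdh at -1.12 ± 0.12. Of 22 extracellular matrix genes, 3 fell (camera adjusted p = 0.353), among them the galectin gene Lgals1, at 285 ± 48.5 CPM (SD, n = 4) against 851 ± 63.7 CPM (SD, n = 3). No cell cycle gene of 18 was called (camera adjusted p = 0.353, and 0.0196 without YAP-M-dIDR replicate 1). Microglia and macrophage genes had 1 higher, the mannose receptor gene Mrc1 by 2.34 ± 0.26, and 1 lower of 16 (camera adjusted p = 0.639). Multiciliated ependymal cell genes had 1 higher of 19 (camera adjusted p = 0.107, 0.0196 without YAP-M tumour replicate 2 and 0.00551 without YAP-M-dIDR replicate 1), with Foxj1, the master regulator of motile cilia, at 12.8 ± 4.29 CPM (SD, n = 4) against 7.55 ± 5.24 CPM (SD, n = 3), or 4.52 CPM without YAP-M-dIDR replicate 1. Neuronal genes had 5 higher, or 6 adjusted over the list alone, and 3 lower of 17 (camera adjusted p = 0.256).

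The remaining lists in this comparison did not pass the camera test either. Notch pathway genes had 2 higher of 13 (camera adjusted p = 0.639), immediate early and stress genes 1 of 12 (0.205) and p53 targets 1 of 11 (0.119, and 0.00386 without YAP-M-dIDR replicate 1). Growth factor receptor genes had 3 higher and 2 lower of 17 (camera adjusted p = 0.758), choroid plexus genes 1 higher of 9, or 0 adjusted over the list alone (0.668), pluripotency genes 2 of 3 measured, or 3 adjusted over the list alone (0.181), and lymphocyte genes none of 3 measured (0.384). For the other lists the counts adjusted over the list alone were the same.

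The genes with the largest rises in YAP-M tumours were AU015836 (7.04 ± 1.19), the serine protease gene Tmprss2 (6.34 ± 1.18), the transcription factor gene Hand1 (6.21 ± 1.33), and Plet1 (5.28 ± 1.18). Without YAP-M-dIDR replicate 3 the fit gave 10.65 for AU015836, but YAP-M-dIDR then had no counts of it, so that size is uncertain. Next were Oit3 (5.08 ± 0.69), the tight junction gene Cldn4 (4.98 ± 0.78), the muscle kinase gene Musk (4.80 ± 0.68) and AC154266.1 (4.76 ± 0.67). Those with the largest falls were the B cell chemokine gene Cxcl13 (-5.33 ± 0.80), Kpna7 (-4.97 ± 0.56), the retinoic acid binding gene Crabp1 (-4.53 ± 0.37), the immunoglobulin heavy chain gene Igha (-4.20 ± 0.67) and Mettl7b (-3.90 ± 0.58). The interferon-induced chemokine gene Cxcl9 (-3.77 ± 0.71), the deiodinase gene Dio3 (-3.75 ± 0.47) and Hoxb8 (-3.63 ± 0.48) were also among them. Their edgeR adjusted p lay between 2.8e-05 (Crabp1) and 0.00455 (Plet1). Several rested on widely spread libraries: Plet1 stood at 35.01 ± 45.5 CPM (SD, n = 4) in YAP-M tumours, or 12.9 CPM without replicate 3.

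The comparison of YAP-M tumour with NSC-YAP set the fusion tumours against cultured progenitors that overexpress YAP. NSC-YAP had almost no RNA of the YAP/TEAD targets Ctgf and Ankrd1, with 240 ± 2.13 CPM of Yap1 (SD, n = 2). Called higher in the tumours were all 16 macrophage genes, all 12 endothelial and pericyte genes, 7 of 9 blood cell genes, 17 of 22 matrix genes and 17 of 19 interferon response genes, and called higher in NSC-YAP were 7 of 14 radial glia genes, among them Sox2, with 2 lower. Each of these list calls was lost with an estimated correlation (adjusted p = 0.235 to 0.393). With edgeR, 5293 genes were called higher and 3951 lower in the tumours. Quantile normalization moved this to 3337 higher and 4173 lower, and moved the median log2 fold change of all genes from 0.10 to -0.14.

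Ctgf rose by 11.81 ± 0.45 (log2, SE), from 0.245 ± 0.0579 CPM (SD, n = 2) in NSC-YAP, and Ankrd1 by 11.44 ± 0.79. The Ankrd1 level in NSC-YAP was 0.651 CPM in replicate 1 and 0.163 CPM in replicate 2, and the rise was 12.75 without the first and 10.75 without the second. Cyr61 rose by 4.71 ± 0.18, from 36.8 ± 2.32 CPM (SD, n = 2). Of the 22 YAP/TEAD targets, 18 rose and 1 fell (median 2.22, camera adjusted p = 4.8e-07, adjusted p = 0.132 with an estimated correlation). Of 18 Hippo pathway components, 7 rose and 2 fell (median 0.44, camera adjusted p = 0.0474, adjusted p = 0.572 with an estimated correlation), with Tead4 up by 5.45 ± 0.48. This list's call was lost without YAP-M tumour replicate 4 (adjusted p = 0.0579), without NSC-YAP replicate 1 (0.0665) and with the compared groups alone (0.0646). Yap1 itself was lower in the tumours at -1.30 ± 0.48 (edgeR adjusted p = 0.0288), a call lost without any 1 of the 6 libraries (0.0502 to 0.0979) and under quantile normalization (0.0625). Mamld1 was not called, at 0.63 ± 0.18.

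All 16 microglia and macrophage genes were higher in the tumours (median 10.81, or 10.70 with members at 0 counts set to their bound, camera adjusted p = 2.71e-10, adjusted p = 0.258 with an estimated correlation), including the protease gene Ctss at 1002 ± 168 CPM (SD, n = 4) against 0.163 ± 0.0578 CPM (SD, n = 2). All 12 endothelial and pericyte genes were higher (median 7.99, or 7.88 at the bound, camera adjusted p = 3.21e-07, adjusted p = 0.235 with an estimated correlation), including Pecam1 by 6.67 ± 0.32. Of 9 blood cell genes, 7 were higher (median 6.87, or 6.03 at the bound, camera adjusted p = 0.00313, adjusted p = 0.393 with an estimated correlation). Of 19 interferon response and antigen presentation genes, 17 were higher (median 6.42, camera adjusted p = 4.8e-07, adjusted p = 0.36 with an estimated correlation), with the regulator gene Irf7 up by 8.15 ± 0.43. Of 22 extracellular matrix and mesenchymal genes, 17 rose and 2 fell (median 4.999, also at the bound, camera adjusted p = 8.49e-05, adjusted p = 0.36 with an estimated correlation), with the collagen gene Col4a2 up by 4.79 ± 0.32.

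Radial glia and neural stem cell genes were lower in the tumours at 7 of 14 members and higher at 2 (median -0.98, camera adjusted p = 0.0191, adjusted p = 0.36 with an estimated correlation, and 0.0981 under quantile normalization). The stem cell transcription factor gene Sox2 stood at 25.2 ± 2.03 CPM (SD, n = 4) against 488 ± 16.7 CPM (SD, n = 2), and Fabp7 was lower at -4.26 ± 0.25. Glycolysis and hypoxia genes were lower at 9 of 15 members and higher at 2 (median -1.72, camera adjusted p = 0.0385, adjusted p = 0.572 with an estimated correlation), including Gapdh (-1.92 ± 0.13) and Hk1 (-2.20 ± 0.08). That call was lost without YAP-M tumour replicate 4 (adjusted p = 0.0547), at a CPM minimum of 5 (0.0531), with the compared groups alone (0.0654) and under quantile normalization (0.204). Notch pathway genes had 4 higher and 8 lower of 13 (camera adjusted p = 0.0506, and 0.0411 to 0.0498 without any 1 of 5 of the 6 libraries, all but YAP-M tumour replicate 4), with the ligand gene Dll3 at -8.25 ± 0.35, the receptor gene Notch1 at -3.86 ± 0.15 and the target gene Hes5 at -8.87 ± 0.56. Oligodendrocyte lineage genes went both ways, 6 higher and 4 lower of 12 (camera adjusted p = 0.783): the progenitor genes Olig1 (-5.60 ± 0.42) and Olig2 (-5.34 ± 0.44) were lower and the myelin gene Mbp higher by 8.11 ± 0.88. Astrocyte genes likewise had 5 higher and 3 lower of 10 (camera adjusted p = 0.528). These included the filament gene Gfap up by 6.80 ± 0.53 and Fgfr3 down at -3.39 ± 0.16.

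Neuronal genes had 10 higher and 4 lower of 17 (camera adjusted p = 0.418), multiciliated ependymal cell genes 8 and 6 of 19 (0.902, turning direction under quantile normalization to a median of -0.04) and cell cycle genes 3 and 0 of 18 (0.418). Immediate early and stress genes had 6 and 3 of 12 (camera adjusted p = 0.437). Choroid plexus genes had 8 higher of 9, or 9 adjusted over the list alone (median 6.86, or 4.53 at the bound, camera adjusted p = 0.0506, 0.0394 without YAP-M tumour replicate 2 and 0.0498 without YAP-M tumour replicate 3). Lymphocyte genes had 3 higher of 3 measured (median 4.26, or 4.20 at the bound, camera adjusted p = 0.125), although Lck stood at -0.0036 under quantile normalization. Growth factor receptor genes had 7 higher and 5 lower of 17 (camera adjusted p = 0.558), with the growth factor gene Igf2 up by 11.31 ± 0.48, while p53 targets had 0 and 3 of 11 (0.358). Coactivator genes had 1 and 2 of 14 (camera adjusted p = 0.125) and pluripotency genes 1 and 2 of 3 measured (0.528). For the other lists the counts adjusted over the list alone equalled those over all genes. The genes with the largest fitted rises had no counts in NSC-YAP, where the fitted fold and so the order are uncertain. Against a floor of 3 counts over that group, the metal transporter gene Slc39a8 was at least 4077-fold higher, Rian at least 3859-fold, the activin gene Inhba at least 3675-fold and Nup62cl at least 2852-fold. Likewise Fcrls was at least 1972-fold higher, Il31ra at least 1811-fold and Prl3a1 at least 1637-fold. AC152063.6, on a scaffold outside the named chromosomes, had nearly the same counts as Rian and is reported as uncertain. Besides Hes5 and Dll3, the largest falls included those at Olfr1349, 1685 times higher in NSC-YAP (95% counting interval 301.5 to 66630), Osr2 (-7.43 ± 0.58), Draxin (-7.02 ± 0.42), Btbd17 (-6.83 ± 0.42) and AC144543.2 (-6.41 ± 0.54).

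**Figure D3:**
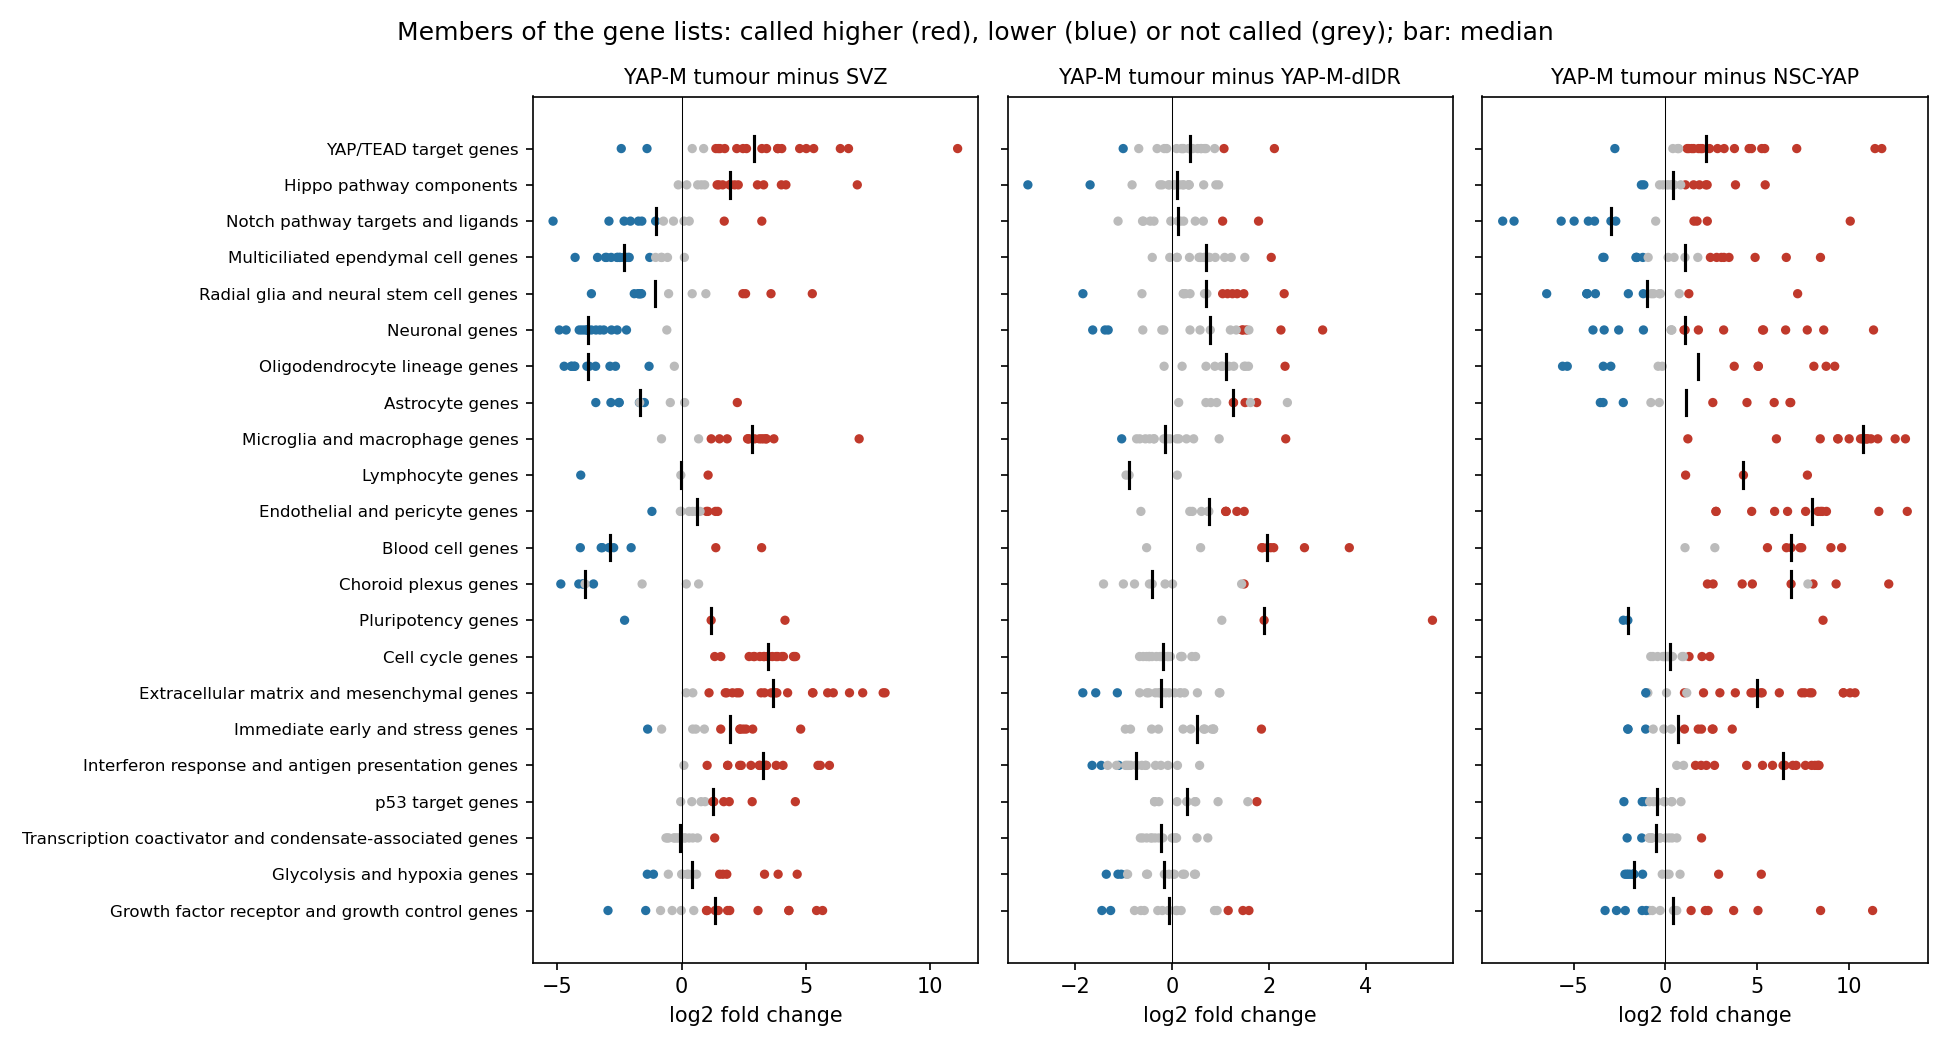
Each point is the log2 fold change of 1 member of a gene list in the 3 comparisons that involve the YAP-M tumours, red where called higher, blue where called lower and grey otherwise, and each bar is the list median. YAP/TEAD targets have medians of 2.92 against SVZ, 0.36 against YAP-M-dIDR and 2.22 against NSC-YAP; the multiciliated list against NSC-YAP changes direction under quantile normalization.

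The comparison of YAP-M-dIDR with NSC-YAP set the ΔIDR construct against cultured progenitors with YAP. Called higher in YAP-M-dIDR were 16 of 22 YAP/TEAD targets, all macrophage and endothelial genes, 7 of 9 blood cell genes and 17 of 22 matrix genes, and each of these list calls was lost with an estimated correlation (adjusted p = 0.234 to 0.471). Sox2, Ptprz1, Dll3 and Olig2 were higher in NSC-YAP. With edgeR, 5026 genes were called higher and 3744 lower; quantile normalization moved this to 3185 and 3807, and the median of all genes from 0.13 to -0.09. Of the 22 YAP/TEAD targets, 16 rose and 1 fell (median 2.35, camera adjusted p = 1.41e-05, adjusted p = 0.234 with an estimated correlation), with Ctgf up by 11.46 ± 0.45, Ankrd1 by 11.60 ± 0.79 (12.88 without NSC-YAP replicate 1 and 10.92 without replicate 2) and Cyr61 by 4.18 ± 0.18. All 16 microglia and macrophage genes were higher (median 10.56, or 10.28 at the bound, camera adjusted p = 9.37e-11, adjusted p = 0.234 with an estimated correlation). So were all 12 endothelial and pericyte genes (median 7.35, or 6.93 at the bound, camera adjusted p = 5.61e-07, adjusted p = 0.234 with an estimated correlation). Of 9 blood cell genes 7 were higher (median 5.03, or 4.21 at the bound, camera adjusted p = 0.0267, adjusted p = 0.471 with an estimated correlation, and 0.166 under quantile normalization). Interferon response genes were higher at 18 of 19 members (median 6.59, camera adjusted p = 1.46e-07, adjusted p = 0.309 with an estimated correlation). Matrix genes were higher at 17 of 22 members and lower at 1 (median 5.13, camera adjusted p = 5.49e-06, adjusted p = 0.234 with an estimated correlation). Hippo components had 8 higher of 18 and Notch pathway genes 4 higher and 8 lower of 13, each with a camera adjusted p = 0.0606. Radial glia and neural stem cell genes had 8 lower and 3 higher of 14 (median -2.13, camera adjusted p = 0.0124, adjusted p = 0.309 with an estimated correlation), with Sox2 at -5.61 ± 0.32 and Ptprz1 at -5.42 ± 0.17. Yap1 was higher by 1.67 ± 0.55 in edgeR (adjusted p = 0.0188), a call lost without YAP-M-dIDR replicate 3 (log2 fold change 1.09) or either NSC-YAP library (1.66 and 1.65), under quantile normalization (1.28) and with the compared groups alone (1.72). Mamld1 was higher by 1.16 ± 0.19. The largest fitted rises, whose order rests on groups with no counts, were at Inhba (at least 5909-fold higher), Prl3a1 (at least 3995-fold), Slc39a8 (at least 3903-fold) and Rian (at least 2857-fold). Falls were largest at Olfr1349 (at least 366-fold lower), Dll3 (-8.89 ± 0.42), Osr2 (360 times lower, 95% counting interval 123 to 1752) and Hes5 (-7.75 ± 0.59).

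The comparison of YAP-M-dIDR with SVZ set the ΔIDR construct against the wild-type samples. Called higher in YAP-M-dIDR were 18 of 22 YAP/TEAD targets, 18 of 18 cell cycle, 19 of 22 matrix, 13 of 16 macrophage and 19 of 19 interferon response genes. Called lower were 15 of 17 neuronal, 11 of 12 oligodendrocyte, 9 of 10 astrocyte, 16 of 19 multiciliated and 7 of 9 blood cell genes, and each of these list calls was lost with an estimated correlation (adjusted p = 0.231 to 0.482). With edgeR, 4932 genes were called higher and 5423 lower. Of the 22 YAP/TEAD targets, 18 rose and 2 fell (median 2.45, camera adjusted p = 8.64e-06, adjusted p = 0.231 with an estimated correlation), with Ankrd1 up by 11.26 ± 0.64, Cyr61 by 6.19 ± 0.17 and Ctgf by 6.04 ± 0.27. The size of the Ankrd1 rise depends on SVZ replicate 3, since its SVZ mean was 0.530 CPM with that library and 0.160 CPM without it. Of 18 Hippo components 12 rose (median 1.84, camera adjusted p = 8.36e-05, adjusted p = 0.411 with an estimated correlation). Yap1 rose by 4.94 ± 0.55. All 18 cell cycle genes were higher (median 3.70, camera adjusted p = 3.28e-07, adjusted p = 0.412 with an estimated correlation). So were 19 of 22 matrix genes (median 3.85, camera adjusted p = 1.57e-06, adjusted p = 0.262 with an estimated correlation) and all 19 interferon response genes (median 3.97, camera adjusted p = 1.94e-06, adjusted p = 0.411 with an estimated correlation). Of 16 macrophage genes, 13 were higher and 1 lower (median 2.998, camera adjusted p = 9.46e-05, adjusted p = 0.426 with an estimated correlation). Of 17 growth control genes, 11 were higher and 4 lower (median 1.68, camera adjusted p = 0.0245, adjusted p = 0.262 with an estimated correlation). Of 15 glycolysis genes, 9 were higher and 1 lower (median 1.12, camera adjusted p = 0.0124, adjusted p = 0.482 with an estimated correlation).

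Lower in YAP-M-dIDR than in SVZ were 15 of 17 neuronal genes, with 1 higher (median -4.54, camera adjusted p = 0.000169, adjusted p = 0.411 with an estimated correlation). Of 12 oligodendrocyte genes 11 were lower (median -4.98, camera adjusted p = 0.000411, adjusted p = 0.473 with an estimated correlation). Of 10 astrocyte genes 9 were lower and 1 higher (median -2.70, camera adjusted p = 0.00691, adjusted p = 0.482 with an estimated correlation). Multiciliated genes were lower at 16 of 19 members (median -2.98, camera adjusted p = 0.000399, adjusted p = 0.482 with an estimated correlation), and blood cell genes at 7 of 9 (median -4.73, camera adjusted p = 0.0102, adjusted p = 0.46 with an estimated correlation). Mamld1 was higher by 1.17 ± 0.16. The largest fitted rises, whose order rests on SVZ with no counts, were at U90926 (at least 1458-fold higher), Cxcl9 (at least 1007-fold), Nkx2-5, a cardiac homeobox gene (at least 652-fold), and Hoxb9 (42.4 ± 16.8 CPM, SD, n = 3, against no counts). The largest falls were at Gpr101 (1031 times lower, 95% counting interval 185 to 40750), the orexin gene Hcrt (502 times lower, 138 to 4148), Scn4b (-8.46 ± 0.58) and the oxytocin gene Oxt (-8.22 ± 1.95). In both comparisons of YAP-M-dIDR the counts adjusted over the list alone equalled those over all genes. The lists not named had camera adjusted p of 0.0606 or more against NSC-YAP and 0.099 or more against SVZ.

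A list's median, mean and test direction differed in sign for 10 of the list tests. These were radial glia (median -1.06, mean 0.06) and coactivator genes (median -0.05, mean 0.03) against SVZ, and Hippo (0.09 and -0.10), choroid plexus (-0.41, test up) and growth control genes (-0.06 and 0.06) against YAP-M-dIDR. They were also pluripotency genes against NSC-YAP (-2.04 and 1.43), multiciliated (0.48), oligodendrocyte (0.58) and astrocyte genes (-0.03 and 0.40), each with the test down, in YAP-M-dIDR against NSC-YAP. The last was that of lymphocyte genes in YAP-M-dIDR against SVZ (0.92 and -0.43). None of these passed the camera test. NSC-YAP was not tested against SVZ here.

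**Figure D4:**
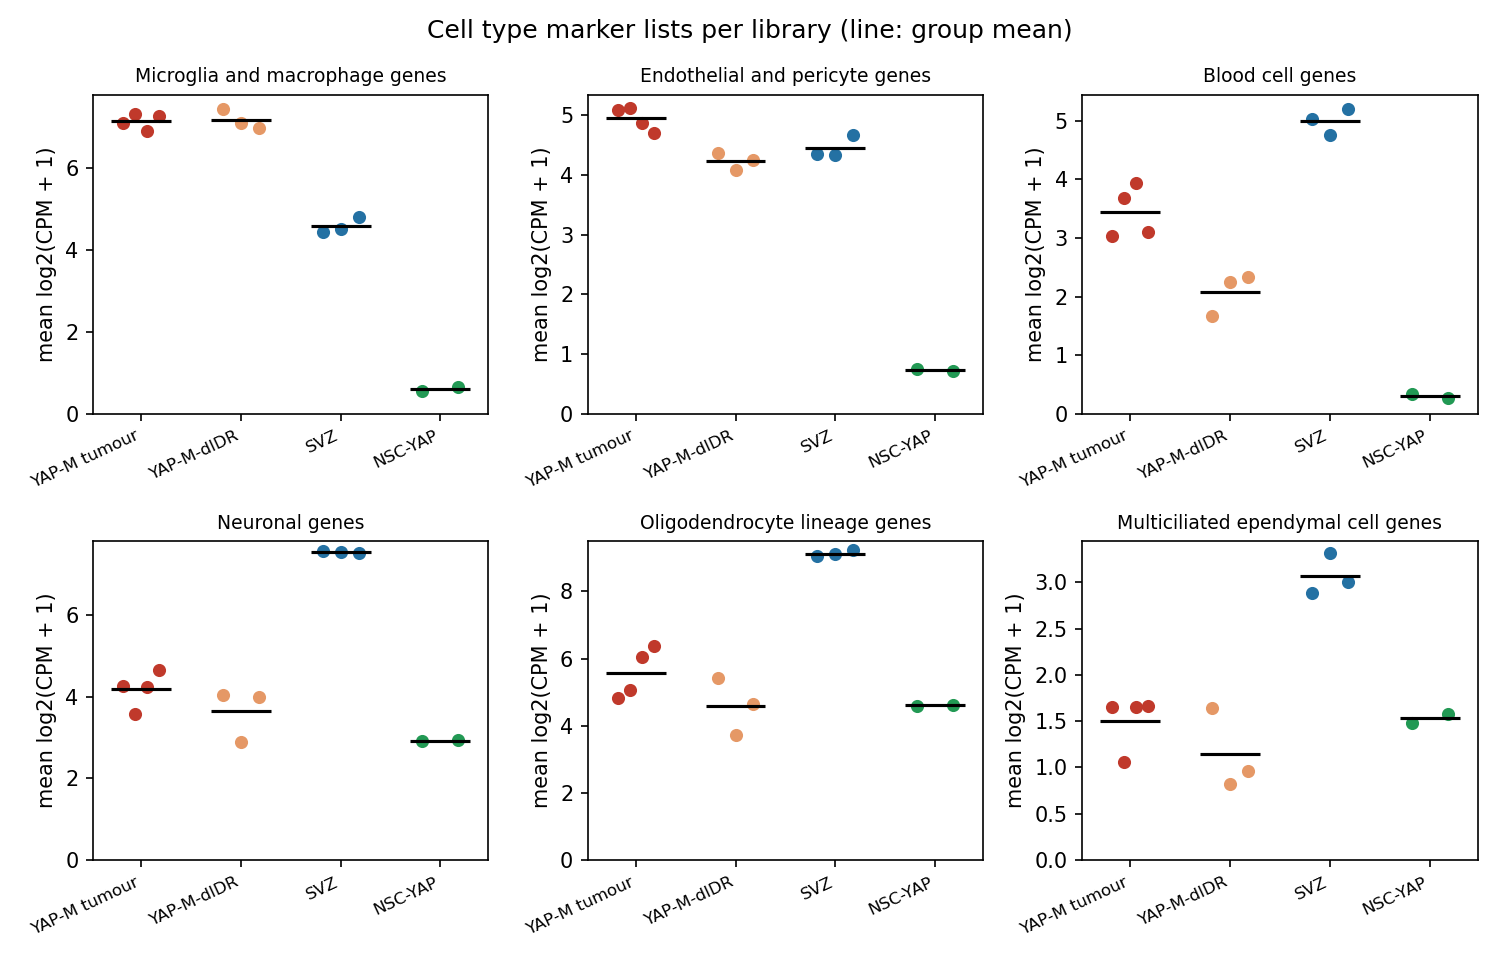
Each point is 1 library and each line a group mean of the mean log2(CPM + 1) over the genes of a cell type list, for 6 lists and 4 groups. The macrophage, endothelial and blood cell lists lie lowest in the 2 NSC-YAP libraries, and the neuronal and oligodendrocyte lists lie highest in SVZ.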

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

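The tests reported here were chosen after the results were seen. Of 77 values tested within the 4 YAP-M tumour libraries, the only group large enough for it, 11 had 1 library far from the other 3. Chance gives about 1 in 20 for independent, normally distributed values. The values here come from the same 4 libraries and include genes with few counts. That share need not hold for them, so 11 was not shown to exceed chance. Replicate 3 had the lowest total count, 20784130 against 24309827 to 24606778. Its mean log2 CPM of extracellular matrix genes was 6.89 against 7.50 to 7.61, Krtap1-5 stood at 191 CPM against 44.3 to 64.1, Dio3 at 0.512 CPM against 1.52 to 1.67 and Hes5 at 0.128 CPM against 0.184 to 0.185. Replicate 2 had a mean log2 CPM of multiciliated ependymal cell genes of 1.06 against 1.65 to 1.66. In that library Panx3 stood at 228 CPM against 134 to 137, Cxcl9 at 6.59 CPM against 2.26 to 2.58, and Olfr1349 at 0.0371 CPM from 1 read against 0. In replicate 4 Dlx6os1 stood at 0.0742 CPM against 0.370 to 0.405 and Hoxb8 at 3.23 CPM against 0.993 to 1.30. A level of 3 counts is 0.128 CPM in replicate 3 and 0.111 CPM in replicate 4. Hes5 and Dlx6os1 lay at or below it in these libraries, so a few reads could set them apart.

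Macrophage, endothelial and blood cell genes in the YAP-M-dIDR libraries bear on their labels, which name both tumour tissue and cultured progenitor cells. Progenitor cells alone were argued against by 35 of 37 measured members called higher than in NSC-YAP. RNA carried over from the YAP-M tumour samples was argued against for the macrophage genes only. They stood at a median of 110% of their YAP-M tumour level, above any share that carry-over would bring. That share is bounded by the transcripts lowest in YAP-M-dIDR: of 62 genes called over 16 times higher in YAP-M tumours, the 18 with at least 5 CPM there, chosen for being low, stood at a median of 3.71%. With 32 of 37 members within 4 times of the YAP-M tumour level, tissue that holds host cells remains a hypothesis from the same data. The blood cell genes went with it least. Of these, 7 of 9 were called higher in YAP-M tumours than in YAP-M-dIDR (median log2 fold change 1.97, highest 3.66). The samples' origin itself was not tested.

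YAP/TEAD target genes were lower in NSC-YAP and SVZ than in YAP-M tumours. Low depth in NSC-YAP was argued against, since the 18 called targets would each have given at least 239 counts there at their YAP-M tumour level. More endothelial cells and pericytes in the tumours than in SVZ were argued against as the whole source, since the upper quartile of that list's log2 fold changes was 1.02 (median 0.62) against a median of 2.92 for the targets. That covers endothelial cells and pericytes against SVZ alone. Against SVZ the matrix and macrophage lists rose by log2 medians of 3.70 and 2.83. Against NSC-YAP the endothelial list rose by a median of 7.99, against 2.22 for the targets. Other host cells as a source of target RNA were therefore not argued against. Culture against tissue, and fusion against YAP itself, stay open, since the design gives each only together with the groups.

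HoxB genes were lower and HoxD genes higher in YAP-M tumours than in YAP-M-dIDR, with medians of -2.77 and 2.50. A single library was argued against, since at least 12 of the 14 called genes stayed called without any 1 of the 7 libraries. RNA of more caudal tissue cannot be told apart. Genes of 1 position, Hoxb8 (-3.63 ± 0.48) and Hoxd8 (3.11 ± 0.48), and Hoxb9 (-3.09 ± 0.41) and Hoxd9 (2.12 ± 0.48), lay at least 5.21 apart, but the pattern itself fixes their opposite signs. The constructs differ by design and may account for it, as may differences between tumours in cell of origin, and neither was tested.

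Splits of the libraries were counted for the number of called genes. For YAP-M tumour against SVZ, 1 of 35 splits, the real one, gave 10018 called genes, and the highest other gave 5862. For YAP-M tumour against YAP-M-dIDR, 1 of 35 gave 3003 and the highest other 1013. In both comparisons this is the smallest share that 35 splits allow, so it argues against chance without excluding it. For YAP-M-dIDR against SVZ the real split gave 10355 and the highest other 0, and 10 splits are too few for a share under 0.05. The comparisons with NSC-YAP have a group of 2 and no such count.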

How the results depend on the processing

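No alternative was added after the results were seen, and the cause of each change below was not tested unless named. Of 162 alternative counts of called genes, 154 lay within 1.5 times of the main count. Direction and call were the same in 1504 of 1667 alternatives of list tests, 7923 of 8114 of named genes and 22 of 36 of the exact test of Yap1. The direction of a list is that of its camera test, so a list can change direction while its median keeps its sign. Of the 55 results that changed direction, 1 (Lck) had an adjusted p under 0.05 in either setting. No gene was called in the opposite direction under any alternative. The adjusted p alone, which drops the limit on size, gave 3768 genes higher and 4199 lower for YAP-M tumour against YAP-M-dIDR, 6326 lower for YAP-M tumour against NSC-YAP and 5792 lower for YAP-M-dIDR against NSC-YAP. A minimum CPM of 5 tests fewer genes and gave 819 lower for YAP-M tumour against YAP-M-dIDR. Quantile normalization gave 1035, 3337 and 3185 higher for YAP-M tumour against YAP-M-dIDR, YAP-M tumour against NSC-YAP and YAP-M-dIDR against NSC-YAP. A pseudocount of 0.1 and the recovery of whole reads were not run because the values are counts, and list tests were not run with DESeq2. With 1 of the NSC-YAP libraries left out, the other is assumed to vary like the other groups.

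Replicate numbers did not clearly pair the samples. The correlation of deviations of libraries with the same number ranged from -0.097 to 0.381 (median 0.0063), and 4 of 15 pairs exceeded 0.1. For libraries with other numbers it ranged from -0.2738 to 0.2585 (median -0.0056), and 4 of 38 pairs exceeded 0.1. Pairing of some samples is therefore not excluded. With the replicate number as a block, genes higher and lower were 4721 and 5396 for YAP-M tumour against SVZ, 1628 and 1297 for YAP-M tumour against YAP-M-dIDR, 5138 and 4069 for YAP-M tumour against NSC-YAP, 4886 and 3766 for YAP-M-dIDR against NSC-YAP, and 4885 and 5466 for YAP-M-dIDR against SVZ. The block ended the list calls for oligodendrocyte (median 0.63) and radial glia genes (0.71) in YAP-M tumour against YAP-M-dIDR, gave a call to choroid plexus genes (6.69) in YAP-M tumour against NSC-YAP, and Trac stood at 0.088 in YAP-M tumour against SVZ.

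With an estimated correlation the 48 called lists lost their call at unchanged medians. These were in YAP-M tumour against SVZ YAP/TEAD targets 2.92, Hippo 1.95, multiciliated -2.32, neuronal -3.75, oligodendrocyte -3.76, macrophage 2.83, cell cycle 3.48, matrix 3.70, immediate early 1.96, interferon 3.28, p53 1.28 and growth control 1.35. They were also in YAP-M tumour against YAP-M-dIDR YAP/TEAD targets 0.36, radial glia 0.69, oligodendrocyte 1.11, astrocyte 1.26, endothelial 0.75, blood cell 1.97 and interferon -0.74. They were also in YAP-M tumour against NSC-YAP YAP/TEAD targets 2.22, Hippo 0.44, radial glia -0.98, macrophage 10.81, endothelial 7.99, blood cell 6.87, matrix 4.999, interferon 6.42 and glycolysis -1.72. They were also in YAP-M-dIDR against NSC-YAP YAP/TEAD targets 2.35, radial glia -2.13, macrophage 10.56, endothelial 7.35, blood cell 5.03, matrix 5.13 and interferon 6.59. They were also in YAP-M-dIDR against SVZ YAP/TEAD targets 2.45, Hippo 1.84, multiciliated -2.98, neuronal -4.54, oligodendrocyte -4.98, astrocyte -2.70, macrophage 2.998, blood cell -4.73, cell cycle 3.70, matrix 3.85, interferon 3.97, glycolysis 1.12 and growth control 1.68.

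Lists that gained a call without a filter on low counts had these medians: in YAP-M tumour against SVZ astrocyte -1.55, endothelial 0.76, blood cell -2.75, choroid plexus -3.73 and glycolysis 0.56, in YAP-M tumour against YAP-M-dIDR multiciliated 0.74, lymphocyte -0.71, pluripotency 2.88, p53 0.37 and glycolysis -0.0908, in YAP-M tumour against NSC-YAP Notch -2.87, lymphocyte 4.65, choroid plexus 6.95 and coactivator -0.42, in YAP-M-dIDR against NSC-YAP Hippo 0.77, Notch -3.54, lymphocyte 5.15, choroid plexus 6.89, p53 -0.46 and glycolysis -0.62, in YAP-M-dIDR against SVZ lymphocyte 2.23, choroid plexus -2.98, immediate early 2.08 and p53 1.30. Results that changed direction without a filter on low counts had these medians or log2 fold changes: in YAP-M tumour against SVZ Trac 0.10, radial glia -0.93, lymphocyte 1.72 and coactivator 0.0803, in YAP-M tumour against NSC-YAP pluripotency 4.80. Lists that lost their call at a minimum CPM of 5 had these medians: in YAP-M tumour against YAP-M-dIDR oligodendrocyte 1.11, in YAP-M tumour against NSC-YAP glycolysis -1.68. Lists that gained a call at a minimum CPM of 5 had these medians: in YAP-M tumour against SVZ blood cell -2.85. Results that changed direction at a minimum CPM of 5 had these medians or log2 fold changes: in YAP-M tumour against YAP-M-dIDR lymphocyte 0.12, in YAP-M tumour against NSC-YAP multiciliated 1.11, in YAP-M-dIDR against SVZ lymphocyte -4.14. Lists that lost their call under median-ratio scaling had these medians: in YAP-M tumour against YAP-M-dIDR radial glia 0.74 and oligodendrocyte 1.14. Lists that gained a call under median-ratio scaling had these medians: in YAP-M tumour against NSC-YAP Notch -2.87. Results that changed direction under median-ratio scaling had these medians or log2 fold changes: in YAP-M tumour against SVZ Trac 0.0495 and coactivator 0.022, in YAP-M tumour against NSC-YAP multiciliated 1.17. Lists that lost their call under quantile normalization had these medians: in YAP-M tumour against NSC-YAP radial glia -0.93 and glycolysis -1.23, in YAP-M-dIDR against NSC-YAP blood cell 0.89. Lists that gained a call under quantile normalization had these medians: in YAP-M-dIDR against NSC-YAP Hippo 0.79. Results that changed direction under quantile normalization had these medians or log2 fold changes: in YAP-M tumour against SVZ Trac 0.0693, pluripotency 0.19 and coactivator 0.0537, in YAP-M tumour against YAP-M-dIDR Ankrd1 0.16, Cd4 -0.11, macrophage 0.022 and growth control 0.0205, in YAP-M tumour against NSC-YAP Lck -0.00355 and multiciliated -0.0443, in YAP-M-dIDR against NSC-YAP Lin28a -0.11 and astrocyte -0.24. Lists that lost their call with the compared groups alone had these medians: in YAP-M tumour against YAP-M-dIDR oligodendrocyte 1.11, in YAP-M tumour against NSC-YAP Hippo 0.49 and glycolysis -1.67. Lists that gained a call with the compared groups alone had these medians: in YAP-M tumour against SVZ astrocyte -1.59, in YAP-M tumour against NSC-YAP Notch -2.92 and choroid plexus 7.41, in YAP-M-dIDR against NSC-YAP Hippo 0.79. Results that changed direction with the compared groups alone had these medians or log2 fold changes: in YAP-M tumour against SVZ Trac 0.0596, pluripotency 1.02 and coactivator 0.0341, in YAP-M tumour against NSC-YAP multiciliated 1.12, in YAP-M-dIDR against SVZ lymphocyte 0.96. Results that changed direction with DESeq2 had these log2 fold changes: in YAP-M tumour against SVZ Trac 0.049.

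Without 1 library at a time, the values ranged as follows for the lists whose call or direction changed (medians), the genes whose direction changed (log2 fold changes), and Yap1 where its exact test changed (difference of mean log2(CPM + 1)). In YAP-M tumour against SVZ Trac -0.16 to 0.42, pluripotency -0.45 to 1.49, coactivator -0.0159 to 0.0667, radial glia -1.08 to -0.89 and Yap1 1.83 to 2.01. In YAP-M tumour against YAP-M-dIDR Cd4 -0.0983 to 0.41, multiciliated 0.32 to 1.5, radial glia 0.62 to 0.86, glycolysis -0.32 to -0.00968, oligodendrocyte 0.66 to 1.76, interferon -0.90 to -0.58, Prlr -1.34 to 2.83, Hippo 0.0693 to 0.22, macrophage -0.31 to -0.00704, cell cycle -0.43 to 0.0815, p53 0.23 to 0.91, YAP/TEAD targets 0.33 to 0.46, choroid plexus -0.93 to 1.20 and Yap1 -3.40 to -2.004. In YAP-M tumour against NSC-YAP Notch -3.12 to -2.73, choroid plexus 6.54 to 7.29, multiciliated 0.92 to 1.40, Hippo 0.44 to 0.51 and glycolysis -1.75 to -1.60. In YAP-M-dIDR against NSC-YAP Hippo 0.72 to 0.77, Notch -4.03 to -3.41, p53 -1.01 to -0.24, astrocyte -0.65 to 0.25 and choroid plexus 4.95 to 7.29. In YAP-M-dIDR against SVZ Nanog -0.21 to 0.39, choroid plexus -4.67 to -2.55 and p53 1.01 to 1.35. The exact p of Yap1 was then 0.0667 to 0.1, since fewer libraries allow no lower one.

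Over the alternatives other than the estimated correlation, the adjusted p in YAP-M tumour against YAP-M-dIDR ranged from 0.00178 to 0.0944 for YAP/TEAD targets, 0.00619 to 0.0717 for radial glia, 0.00867 to 0.234 for oligodendrocyte, 0.00146 to 0.14 for interferon, 0.0196 to 0.81 for cell cycle, 0.00818 to 0.228 for glycolysis, 0.00551 to 0.489 for multiciliated and 0.00386 to 0.376 for p53 lists. Against NSC-YAP it ranged in YAP-M tumour from 0.00189 to 0.0665 for Hippo, 0.00219 to 0.204 for glycolysis, 0.000796 to 0.0981 for radial glia, 0.00484 to 0.0713 for Notch and 0.00695 to 0.113 for choroid plexus lists, and from 1.65e-05 to 0.0979 for Yap1. In YAP-M-dIDR it ranged from 0.000851 to 0.166 for blood cell genes and from 3.26e-06 to 0.0976 for Yap1. Depth limits folds at genes near the floor of 0.11 to 0.147 CPM per library.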

Other observations

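All genes and values here were chosen after the data were seen. Hox genes, which pattern the body axis behind the forebrain, were nearly silent in SVZ and had counts in both tumour-construct groups. Some levels were low, with Hoxb2 at 0.163 CPM and Hoxb3 at 0.280 CPM in YAP-M tumours. A Hox gene was tested only with at least 1 CPM in 2 libraries, which the SVZ libraries did not give. Calls above SVZ were therefore largely fixed in advance by this filter. All 10 HoxA, 9 HoxB, 7 HoxC and 6 HoxD genes measured were called higher in YAP-M tumours than in SVZ, with median log2 fold changes of 6.27, 5.17, 4.69 and 7.57 when members with no counts in SVZ are set to their lower bound (fitted medians 7.38, 8.20, 7.57 and 10.19). Against YAP-M-dIDR, 8 of 9 HoxB genes were lower and all 6 HoxD genes higher, while 1 of 10 HoxA genes was higher and 3 of 7 HoxC genes were lower. Hoxb9 stood at 4.96 ± 2.56 CPM (SD, n = 4) in YAP-M tumours and 42.4 ± 16.8 CPM (SD, n = 3) in YAP-M-dIDR, and Hoxd13 at 66.6 ± 19.6 CPM and 11.98 ± 12.2 CPM, or 5.10 CPM without YAP-M-dIDR replicate 1. NSC-YAP expressed HoxA genes such as Hoxa5 (27.1 ± 1.53 CPM, SD, n = 2), and had no counts for all 9 HoxB and all 7 HoxC genes measured.

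Imprinted genes, which are expressed from 1 parental copy, were looked at for 8 chosen genes. In YAP-M tumours 7 of them were called higher and 1 lower than in NSC-YAP, and 3 higher and 4 lower than in SVZ. Against YAP-M-dIDR only 2 were higher and 2 lower. The growth factor gene Igf2 stood at 2865 ± 526 CPM (SD, n = 4) in YAP-M tumours, 7827 ± 2207 CPM (SD, n = 3) in YAP-M-dIDR, 144 ± 35.3 CPM (SD, n = 3) in SVZ and 1.12 ± 0.376 CPM (SD, n = 2) in NSC-YAP. H19, its neighbour, stood at 238 ± 68.7, 77.7 ± 43.2, 1.40 ± 0.160 and 0.244 ± 0.000268 CPM (SD) in the same groups and order. The non-coding RNA gene Meg3 stood at 261 ± 75.5 CPM (SD, n = 4) in YAP-M tumours, 256 ± 131 CPM (SD, n = 3) in YAP-M-dIDR and 3032 ± 322 CPM (SD, n = 3) in SVZ, and at 0.0814 CPM, from 4 counts, in NSC-YAP, where Rian had no counts. Prl3a1, a gene of the placental prolactin family, stood at 101 ± 33.1 CPM (SD, n = 4) in YAP-M tumours and 246 ± 118 CPM (SD, n = 3) in YAP-M-dIDR, against 3 counts in all SVZ libraries and none in NSC-YAP. The epithelial keratin genes Krt8 and Krt18 stood at 224 ± 212 CPM and 423 ± 308 CPM in YAP-M tumours (SD, n = 4), or 122 and 273 CPM without replicate 3, against 8.33 ± 3.13 CPM and 91.9 ± 27.7 CPM in YAP-M-dIDR (SD, n = 3). The SVZ libraries held RNA of genes known from other forebrain regions, with the dopamine receptor gene Drd2 at 76.5 ± 4.16 CPM, the oxytocin gene Oxt at 18.96 ± 8.94 CPM and the choroid plexus gene Ttr at 1756 ± 739 CPM (SD, n = 3).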
